A study of Zea mays with 33 samples.

How the data were processed

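RNA-seq libraries of maize B73 roots were made with a directional kit from total RNA, per the labels' protocols. The authors deposited 1 table of FPKM (fragments mapped to a transcript, scaled to its length and to the library's mapped fragments), with 1 column for each of the 33 libraries and no pooling of replicates. The maize build B73 RefGen_v4, TopHat2 2.1.0 and HTSeq 0.6.1 are named, per the submitters' processing notes, without their roles. The program that made the FPKM values, and how reads of fungus and plant were separated, are not given in the sources used here. All columns were matched to a sample by name. Groups were taken from the sample labels: untreated roots at 6 h (replicates 1, 2 and 4), and roots with *T. virens* at 6, 30 and 54 h (replicates 1 to 10 each).

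The table has 41942 rows. The 1 row with a blank identifier was left out, which held 0 to 0.0039% of a library's FPKM, and 41941 remained. Low values were not whole multiples of a common step, so reads could not be recovered and the depth of the libraries is unknown. No 2 columns were identical. Over the 1903 genes above 0 in every library, as log2(FPKM + 1), the highest correlation between 2 libraries was 0.973.

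FPKM values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend and robust estimation). All 33 libraries entered 1 model with 4 group means. Genes at 1 FPKM or more in at least 3 libraries were tested, 14224 in all. Tests were two-sided, and calls were made at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison, with the number at 2-fold or more beside it. Log2 differences are on the log2(FPKM + 1) scale, which understates the change of low genes. Totals of FPKM over the loci of a microRNA family, for the 18 families at 1 FPKM or more in at least 3 libraries, were compared on the same scale by two-sided permutation tests in SciPy 1.17.1, exact against untreated roots and with 100000 resamples for 10 against 10, and adjusted over the 18 families of a comparison. These family tests and the test of genes listed were chosen after seeing the data.

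The limma fit was tested on simulated data, drawn for 14224 genes from the real means and spreads. At 6 h against untreated roots, it recovered 0 of 68 genes changed 2-fold, 14 of 66 changed 4-fold and 32 of 66 changed 16-fold, and called 6 unchanged genes. For 30 h against 6 h it recovered 6 of 68, 24 of 66 and 57 of 66 with 7 unchanged genes called, and for 54 h against 30 h it recovered 8 of 68, 22 of 66 and 50 of 66 with 7. In these simulations a change of 2-fold was therefore mostly not called. They changed few genes and drew normal values without the zeros of the data. The real comparisons called many more genes, which eases the adjusted threshold, and calls under 2-fold did occur in them. From 6 to 30 h, for example, 2849 genes fell, 2229 of them by 2-fold or more.

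Gene names came from a RefSeq table of the assembly Zm-B73-REFERENCE-NAM-5.0, another build than that of the files, so no coordinates are given. It matched 153 of the 154 microRNA loci and 0 of the 41613 and 174 other identifiers of the 2 other kinds. As a result 0 of the 25 gene lists fixed before the data were examined had a member, and the planned tests of lists could not be run. These lists covered jasmonate, ethylene, pathogenesis-related proteins, benzoxazinoids, terpenoids, lignin, transport, cell wall, stress, clock and other groups. The rule for named genes, also fixed before the data were examined, took per comparison and direction up to 8 called genes with a name and a mean of at least 5 FPKM in the higher group, by size of change, and at most 2 genes known by identifier only. Named loci outside this rule are marked as chosen after their values were seen.

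The alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, median-ratio scaling, quantile normalization, only the 2 groups compared, limma array weights, the replicate number as a block, and leaving out each untreated replicate. Added after seeing the data were genes above 0 in every library (1903 genes, with and without scaling), zeros as missing (8624 genes with at least 2 values above 0 in every group), leaving out the libraries listing under 5000 genes, and leaving out the 3 libraries of 30 h whose profile lay nearer another group. The family totals were also compared after quantile normalization over the genes tested, and held only the loci tested there. The level above which 95% of genes were listed in treated libraries was first sought with a logistic curve. It gave a level of 4.77e+08 FPKM at 6 h, because the share listed did not rise steadily with level, and that value was discarded. The level was then read from classes that double in FPKM, a change made after seeing the first result. Python 3.11.15 and matplotlib 3.10.9 were also used.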

Results

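RNA was sequenced from roots of the maize inbred line B73, grown in liquid medium, that were left untreated or met living mycelium of *Trichoderma virens*, a root-colonizing soil fungus known for inducing systemic resistance in its host. The series was made to find gene networks of plant and fungus in early and late contact, and the table analysed here holds maize genes. It has 33 libraries: 3 of untreated roots at 6 h, and 10 each of roots with the fungus at 6, 30 and 54 h. Untreated roots of 30 and 54 h were not analysed here, so the effect of the fungus is separated from that of time only at 6 h. The values are FPKM as deposited, without read counts, so the depth of each library is unknown and no counting interval is given. The labels do not say whether replicates came from separate plants or cultures. The p-values therefore measure only the spread between these samples, which may be technical.

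The libraries differed in how many genes they listed above 0. Untreated libraries listed 16759 ± 852 genes (SD, n = 3) and treated libraries of 6 h listed 11399 ± 1300 (SD, n = 10), a difference of -5360 genes (two-sided exact permutation test, p = 0.007). The libraries of 30 h listed 7190 ± 3876 genes (SD, n = 10), from 3402 to 12787, and those of 54 h listed 7178 ± 2096 (SD, n = 10). Under 5000 genes were listed in 5 libraries of 30 h (replicates 1, 6, 7, 8 and 9) and in 1 of 54 h (replicate 3). The totals of FPKM per library ran from 40799 to 265405. Zeros were not limited to weakly expressed genes: of the 273 genes with a median of at least 100 FPKM over all libraries, 139 were at 0 in at least 1 library. A value of 0 is therefore described below as listed at 0, since it can be a failed estimate.

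**Figure D1:**
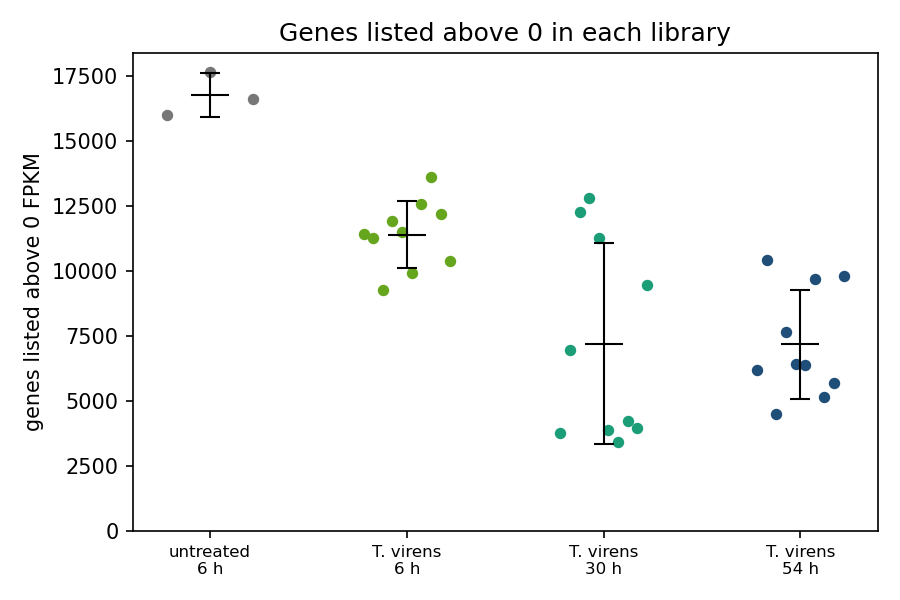
Number of genes listed above 0 FPKM (y axis) in each library, by group (x axis); each point is 1 library, the horizontal bar is the mean and the whisker is 1 SD (n = 3 untreated, n = 10 in each other group). Untreated libraries lay between 15983 and 17671 genes, and the 30 h group ran from 3402 to 12787.

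How often a gene was listed in the treated libraries did not rise steadily with its level in untreated roots. Among the 13217 genes above 0 in all 3 untreated libraries, 76% of the values of genes under 1 FPKM were above 0 in the 6 h treated libraries. The share was 65.9% for genes of 4 to 8 FPKM, 81.4% for genes of 16 to 32 FPKM and 97.3% for genes of 64 to 128 FPKM. At 30 h the share was 44.6% for genes of 4 to 8 FPKM and 88.7% for those of 256 FPKM and over, and at 54 h it was 42.7% and 92.5%.

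**Figure D2:**
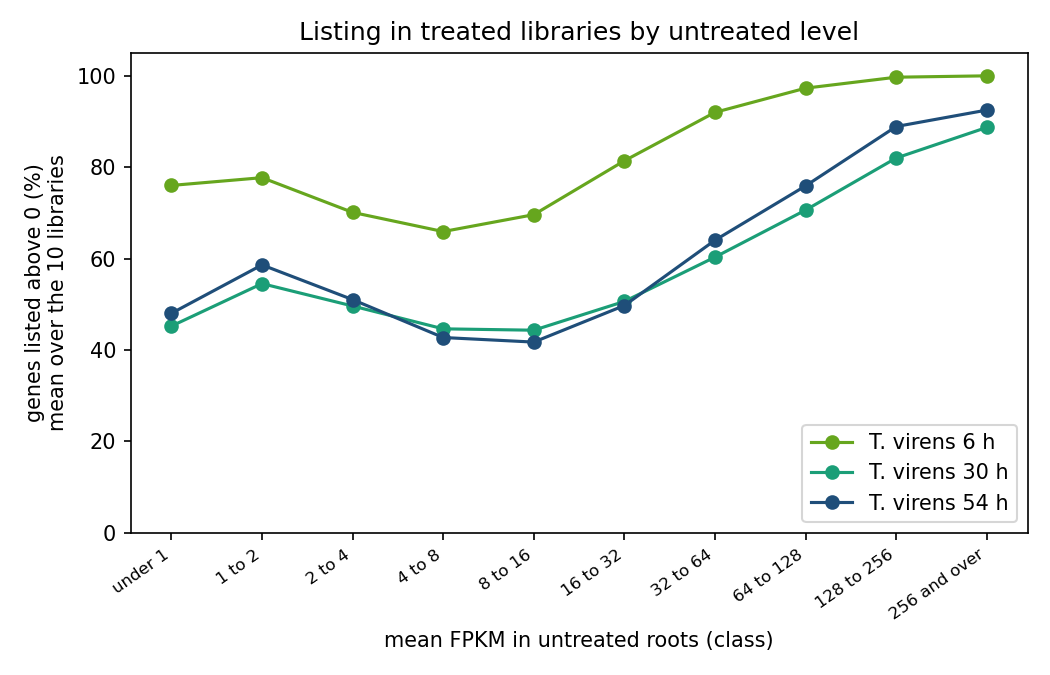
Percent of genes listed above 0 (y axis, mean over the 10 libraries of a group) by the class of mean FPKM in untreated roots (x axis, classes that double), for the 3 groups with the fungus. Each line dips at intermediate levels, with 65.9% at 4 to 8 FPKM at 6 h, and rises toward the highest class.

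The comparison of roots with and without the fungus at 6 h asked which maize genes changed in early contact. The 2 genes with the largest rise are known here by identifier only. Zm00001d018737 was at 42.3 ± 29.1 FPKM with the fungus (SD, n = 10) against 0.903 ± 0.97 in untreated roots (SD, n = 3), a log2 difference of 4.27 (SE 0.86; limma adjusted p = 0.00041). Zm00001d037877 was at 115 ± 26.1 FPKM (SD, n = 10), a log2 difference of 4.20 (SE 0.68; limma adjusted p = 1.9e-05). Its untreated values were 0.391, 116 and 0.437 FPKM in replicates 1, 2 and 4, so 1 untreated library was at the treated level, and without it the log2 difference was 6.32. Zm00001d005250 and Zm00001d053881 had the largest falls: their untreated values ran from 46.9 to 84.7 and from 40.2 to 53 FPKM, and all 10 treated libraries listed both at 0 (limma adjusted p = 6.3e-26 and 3.9e-06). These p-values depend on the spread of the later groups, which the model shares. All 10 libraries of 30 h and all 10 of 54 h also listed Zm00001d005250 at 0. Its p-value therefore reflects no spread between treated libraries. With only the 2 groups compared, limma adjusted p was 7e-10 for both falls, again with constant zeros in the treated group. It was 0.001 for Zm00001d018737 and 0.013 for Zm00001d037877.

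The values of a microRNA locus, here and below, are FPKM of fragments mapped to that locus. Mature microRNAs and their action on targets were not measured. Of the 39 microRNA loci tested, 2 fell and 0 rose at 6 h (limma), and at an unadjusted p under 0.05 the counts were 5 lower and 1 higher. Both were under 5 FPKM and are named after their values were seen. zma-MIR166c, of the family that targets class III HD-ZIP transcription factors, was at 2.61 to 3.84 FPKM in untreated roots and at 0 to 3.36 FPKM with the fungus (log2 difference -1.41, SE 0.41, limma adjusted p = 0.015). zma-MIR395o, of the family induced by sulfate starvation, was at 0.723 to 4.29 FPKM in untreated roots and at 0 to 0.71 FPKM with the fungus (log2 difference -1.25, SE 0.28, limma adjusted p = 0.0014). The fall of zma-MIR166c passed the test under 7 of 13 alternative settings and that of zma-MIR395o under 11 of 13. With quantile normalization the log2 differences were -0.16 and -0.24 (limma adjusted p = 0.79 and 0.8; 0.0019 to 0.79 and 0.00032 to 0.8 over all alternatives).

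In all, 319 genes rose and 2093 fell at 6 h among 14224 tested (limma, adjusted p under 0.05), 293 and 1986 of them by 2-fold or more. Of the fallen genes, 2074 were listed at 0 in at least 1 treated library and 426 in all 10, whereas 308 of the risen genes were above 0 in all 10. Quantile normalization gave 280 rises and 1078 falls, and a fit of only the 2 groups compared gave 753 and 1302. Array weights lowered the rises to 189, and leaving out the libraries listing under 5000 genes raised them to 609. Among the 1903 genes above 0 in every library, a choice made after seeing the data, 284 rose and 0 fell by limma, and 173 rose and 64 fell after median-ratio scaling. With zeros taken as missing, 859 rose and 47 fell. These settings leave out genes or values by the zeros themselves, so most falls were removed by construction, and they describe only genes or values above 0. Without untreated replicate 1 the rises numbered 96 in place of 319, and without untreated replicate 2 the calls numbered 1568 in place of 2412.

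From 6 to 30 h of contact, the largest rises were those of Zm00001d031157 and Zm00001d031155. Zm00001d031157 was at 1.13 ± 1.12 FPKM at 6 h (SD, n = 10) and at 110 ± 79.6 at 30 h (SD, n = 10), a log2 difference of 5.29 (SE 0.42; limma adjusted p = 7.1e-10). Zm00001d031155 was at 1.12 ± 1.12 and 102 ± 73.2 FPKM (SD, n = 10 in each), a log2 difference of 5.18 (SE 0.42; limma adjusted p = 7.1e-10). The 2 identifiers differed by no more than 0.01 FPKM in 13 of the 33 libraries. If they are near-identical copies, the division of reads between them is uncertain. Both stayed high at 54 h, at 115 ± 34.1 and 106 ± 35.2 FPKM (SD, n = 10). Zm00001d033855 and Zm00001d015905 fell from 31 to 88.8 FPKM and from 30.9 to 134 FPKM at 6 h, and were listed at 0 in 9 and 8 of the 10 libraries of 30 h (limma adjusted p = 3.5e-05 and 1.1e-05).

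Among the microRNA loci, 2 fell and 0 rose at 30 h by limma, with 6 lower and 1 higher at an unadjusted p under 0.05. Both are under 5 FPKM and were named after their values were seen. zma-MIR168b, of the family that targets ARGONAUTE1, had a log2 difference of -1.22 (SE 0.42; limma adjusted p = 0.038) and was listed at 0 in 5 libraries of 30 h. zma-MIR167g, of the family that targets auxin response factors, had a log2 difference of -0.97 (SE 0.34; limma adjusted p = 0.043) and was listed at 0 in 4. They passed the test under 3 of 10 and 3 of 9 alternative settings in that order, with limma adjusted p up to 0.87 and 0.92. Without the libraries listing under 5000 genes, the log2 differences shrank to -0.34 and -0.44 (limma adjusted p = 0.87 and 0.76).

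At 30 h, 95 genes rose and 2849 fell against 6 h (limma, adjusted p under 0.05), 68 and 2229 of them by 2-fold or more. Without the libraries listing under 5000 genes, left out after seeing the data, 47 rose and 84 fell. Median-ratio scaling gave 163 rises and 1355 falls, quantile normalization gave 1206 and 818, and array weights gave 148 and 4683. The genes above 0 in every library gave 80 rises and 630 falls, and 186 and 133 after scaling, which centres these genes (median log2 difference -0.43 before and 0.02 after). With zeros taken as missing, 151 rose and 712 fell.

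From 30 to 54 h, 3 of the 39 microRNA loci tested rose. zma-MIR408b, of a copper-responsive family that targets laccases and plantacyanins, ran from 1.49 to 34.7 FPKM at 54 h (median 20.2) and from 0 to 14.8 at 30 h (median 1.4), a log2 difference of 2.03 (SE 0.57; limma adjusted p = 0.036). zma-MIR398a, of a copper-responsive family that targets copper/zinc superoxide dismutases, ran from 0.0135 to 20.1 FPKM at 54 h and from 0 to 3.37 at 30 h, a log2 difference of 1.62 (SE 0.47; limma adjusted p = 0.042). zma-MIR169i, of a family that targets NF-YA transcription factors, is under 5 FPKM and was named after its values were seen (log2 difference 1.29, SE 0.36, limma adjusted p = 0.036). By limma 0 loci fell, with 6 higher and 1 lower at an unadjusted p under 0.05. These 3 calls were near the threshold: they passed under 2, 4 and 3 of 10 alternative settings in that order, with limma adjusted p up to 0.19, 0.5 and 0.14.

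The identifiers with the largest rises at 54 h were Zm00001d042114, at 174 to 692 FPKM and listed at 0 in 9 libraries of 30 h, and Zm00001d036542, at 170 to 691 FPKM and likewise listed at 0 in 9 (limma adjusted p = 1.6e-07 and 5e-07). Zm00001d049129 fell and was listed at 0 in all 10 libraries of 54 h and in 4 of 30 h (limma adjusted p = 0.02), a call that was lost with only the 2 groups compared (limma adjusted p = 0.061; at most 0.061 over its 9 alternatives). Zm00001d018737, which had risen at 6 h, fell by 2.87 on the log2 scale (SE 0.58; limma adjusted p = 0.0021), to between 0 and 10.3 FPKM. At 30 h its values fell into separate levels: replicates 3, 4 and 10 were between 88.1 and 90.4 FPKM, and the other 7 were between 4.42 and 9.36.

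**Figure D3:**
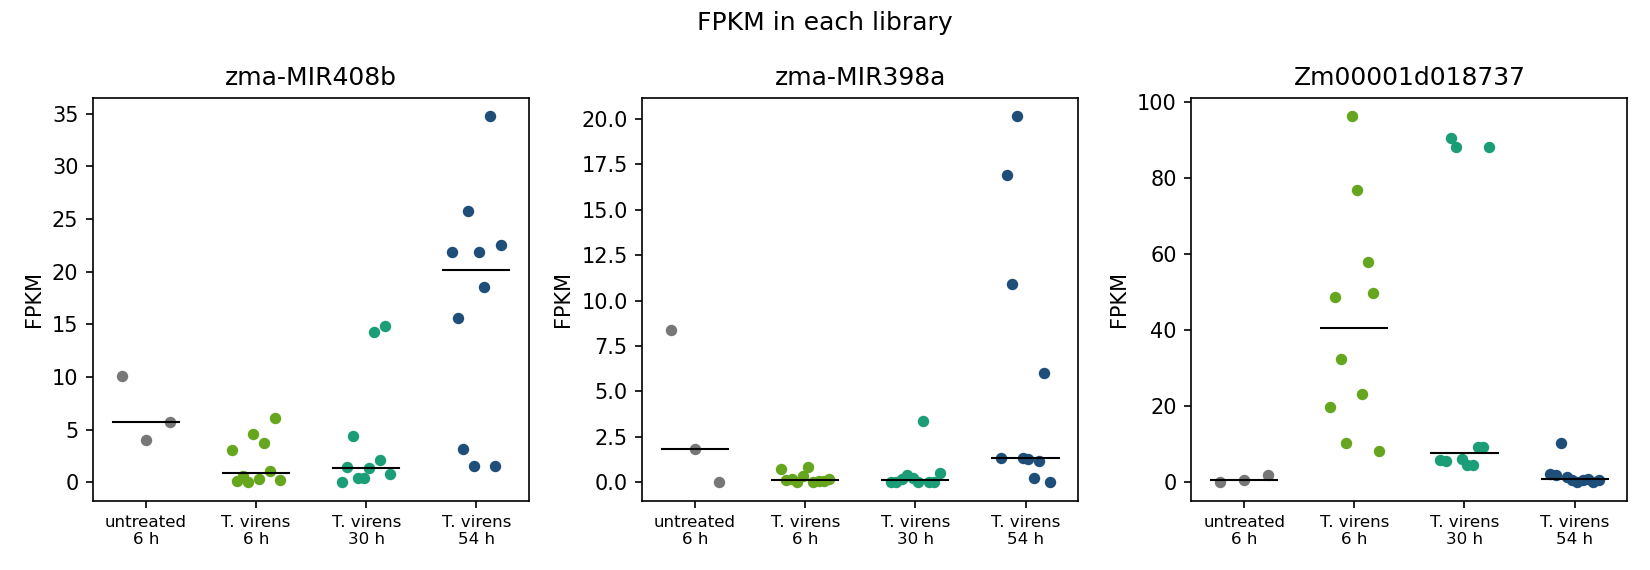
FPKM (y axis) of zma-MIR408b, zma-MIR398a and Zm00001d018737 in each library, by group (x axis); each point is 1 library and the horizontal line is the median of the group. zma-MIR408b reached 34.7 FPKM at 54 h, and Zm00001d018737 lay between 8.15 and 96.2 FPKM at 6 h with the fungus and between 0 and 10.3 at 54 h.

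At 54 h, 554 genes rose and 28 fell against 30 h (limma, adjusted p under 0.05), 431 and 23 of them by 2-fold or more. The split moved with the libraries and the scaling: 405 rose and 457 fell without the libraries listing under 5000 genes, 328 and 93 after median-ratio scaling, and 188 and 42 after quantile normalization. Among genes above 0 in every library 456 rose and 26 fell, and 255 and 191 after scaling (median log2 difference 0.30 before and -0.03 after). With zeros taken as missing, 775 rose and 138 fell.

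**Figure D4:**
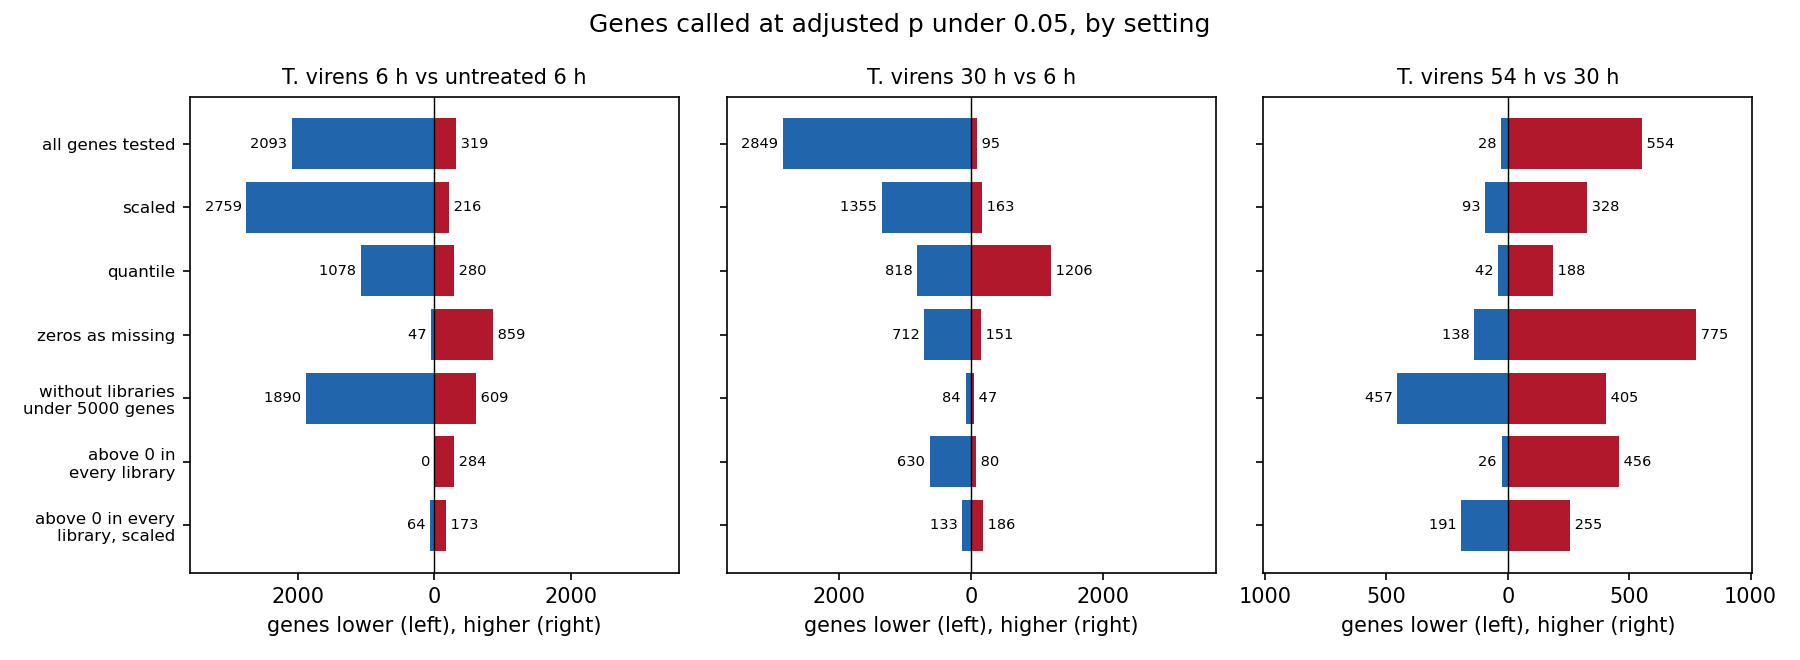
Genes lower (left, blue) and higher (right, red) at adjusted p under 0.05 (x axis, number of genes; its range differs between the 3 panels) for the main setting and 6 alternatives (y axis). At 6 h the falls numbered 2093 over all genes tested and 0 among genes above 0 in every library.

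Over the whole span, 457 genes rose and 2699 fell from 6 to 54 h (limma, adjusted p under 0.05), 307 and 2284 of them by 2-fold or more. Among genes above 0 in every library the numbers were 276 and 307, and 382 and 284 after scaling. With zeros taken as missing they were 735 and 876, and quantile normalization over all genes gave 1743 and 1381. Of the 39 microRNA loci tested, 2 rose and 3 fell from 6 to 54 h (limma). The falls had means under 5 FPKM and are named after their values were seen. They were zma-MIR167g (log2 difference -1.84, SE 0.34, limma adjusted p = 0.00035) and zma-MIR156g (-1.46, SE 0.47, limma adjusted p = 0.024). The third was zma-MIR168b (-1.14, SE 0.42, limma adjusted p = 0.046). All 10 libraries of 54 h listed zma-MIR167g at 0, which can be a failed estimate. Alternative settings were not compiled for these 3 falls. zma-MIR408b was higher at 54 h than at 6 h by 2.45 (log2, SE 0.57; limma adjusted p = 0.0032) and zma-MIR398a by 1.70 (SE 0.47; limma adjusted p = 0.011). zma-MIR398b differed by 1.78 (SE 0.69; limma adjusted p = 0.061) and did not pass the test. Neither zma-MIR408b (0.80, SE 0.84, limma adjusted p = 0.45) nor zma-MIR398a (0.41, SE 0.69, limma adjusted p = 0.65) passed the test at 54 h against untreated roots of 6 h.

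Against untreated roots of 6 h, where hours and fungus differ together, 239 genes rose and 4490 fell at 30 h, and 747 rose and 5330 fell at 54 h (limma, adjusted p under 0.05). At 2-fold or more the numbers were 218 and 4242 at 30 h, and 654 and 5083 at 54 h. Among genes above 0 in every library they were 165 and 90 at 30 h and 496 and 120 at 54 h, and after scaling 277 and 130 at 30 h and 469 and 373 at 54 h. With zeros taken as missing they were 541 and 146 at 30 h and 1545 and 583 at 54 h. Quantile normalization gave 1792 and 1804 at 30 h, and 2665 and 2708 at 54 h. Without untreated replicate 1 the rises numbered 86 at 30 h and 418 at 54 h. Without untreated replicate 2 the calls numbered 2405 in place of 4729 at 30 h and 3863 in place of 6077 at 54 h, and without replicate 4 they numbered 3147 at 30 h.

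Of the 319 genes higher at 6 h, 114 were also higher at 30 h and 208 at 54 h against the same untreated libraries, where independent lists would share 5.4 and 16.8. Of the 2093 lower genes, 2059 and 2081 were also lower, where independent lists would share 660.7 and 784.3. Simulated unchanged groups shared 0 called genes on average in 20 simulations, since almost none were called. Lists of the real sizes, taken from the top of each simulated comparison, shared 106.1 and 202.2 higher genes and 1762.1 and 1862.6 lower genes through the shared untreated libraries alone. For genes above 0 in every library, after scaling, 110 and 134 higher genes were shared against 117 and 145.8 in such simulated lists. The lower genes shared were 36 and 56 against 40.4 and 57, so no excess over the shared controls was seen there. The untreated libraries are too few to be split, so much of these overlaps may come from the shared controls. With the 30 h libraries divided so that the steps shared none, 121 genes fell from 6 to 30 h (replicates 1 to 5) and 795 rose from 30 to 54 h (replicates 6 to 10). Both lists held 32 genes, where independent lists would share 6.8. In the reverse division the lists of 4895 and 319 genes shared 83, below the 109.8 of independent lists. These divisions are not equal repeats. Among replicates 6 to 10 of 30 h, all but replicate 10 listed under 5000 genes, and among replicates 1 to 5 only replicate 1 did. Whether this imbalance gave the different lists and overlaps was not tested. Among genes above 0 in every library, after scaling, the shared genes numbered 23 and 19 where independent lists would share 8.1 and 21.5.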

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

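The tests of explanations were set down before their results were seen, with some exceptions. The level in the first pattern was read in another way after a first fit had failed. A binomial test that was not in the rule set down was added for well expressed genes at 6 h. The fits without replicates 4, 5 and 7 of 30 h were chosen after the results were seen. Each group of 10 libraries was searched for a library far from the others, and 20 of 56 groups searched had one, where chance gives about 1 in 20. Zeros make such gaps easy, since 1 library above 0 among 9 at 0 always stands apart.

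Replicate 4 of 30 h stood apart in 5 genes. It was at 39.5 FPKM for Zm00001d053881, 34.6 for Zm00001d033855 and 18.8 for Zm00001d042114, with the other 9 libraries listed at 0, at 99.3 for Zm00001d049129 with the next at 51, and at 3.45 for zma-MIR166c with the next at 0.65. Replicate 7 of 30 h was at 435 FPKM for Zm00001d036542, with the other 9 at 0, and at 3.37 for zma-MIR398a with the next at 0.484. Replicate 9 of 30 h was at 4.88 FPKM for zma-MIR169i.

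At 54 h, replicate 3 was at 10.3 FPKM for Zm00001d018737, replicate 10 at 27.8 for Zm00001d053881, replicate 6 at 1.19 for zma-MIR395o, replicate 8 at 4.68 for zma-MIR168b and replicate 4 at 9.51 for zma-MIR169i. At 6 h with the fungus, replicate 1 was at 3.36 FPKM for zma-MIR166c, replicate 7 at 0.71 for zma-MIR395o and at 3.36 for zma-MIR169i, and replicate 5 at 45.3 for Zm00001d036542. Replicate 6 of that group was at 4.25 for both Zm00001d031157 and Zm00001d031155, and replicate 3 was at 15.9 for the MIR398 family total.

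Most calls at 6 h against untreated roots were falls. Library scaling as their whole source is argued against by quantile normalization alone, which lowered the 2093 falls to 1078 but left them the majority over 280 rises. Median-ratio scaling gave 2759 falls but could hardly have lowered them. A scale factor leaves a 0 at 0, and 2074 of the fallen genes were at 0 in at least 1 treated library. A listing limit stays open, since 0.1% of the fallen genes lay at 64 FPKM or more, where over 95% of genes were listed, but only 4% of all tested genes lay there, so this test could hardly have come out otherwise. The dip in listing at 4 to 8 FPKM is not what a limit set by FPKM alone would give, and gene lengths were not used here. Fewer transcripts of well expressed genes also stays open: at 20 FPKM or more, 72 genes fell and 74 rose (two-sided exact binomial test, p = 0.93), whereas below it 2021 fell and 245 rose (Fisher's exact test between the levels, p = 6e-30). By the rule set down, rises outnumbering falls at 20 FPKM or more, with Fisher's exact p under 0.05, counted against this explanation, and both held. The binomial test was not part of that rule. By it 74 rises and 72 falls could not be told apart, so no conclusion is drawn.

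Most calls at 30 h against 6 h were falls too. Without the 5 libraries of 30 h listing under 5000 genes, 75 falls were called, and without the other 5 libraries of 30 h, 6246 were, which is consistent with those libraries as the source of most falls. Leaving out replicates 4, 5 and 7 of 30 h as well, whose profiles lay nearer another group, gave 104 falls with 3 libraries left and 5798 with 4. Whether their few listed genes came from the library or from the roots cannot be told apart by this count, and no biological explanation was tested.

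For each of the 6 comparisons, 1 of 100 splits of its libraries, the real one, gave as many calls. A random division of these libraries therefore seldom gave such a count, although 100 splits cannot show a share under 1 in 100. The splits also treat the libraries as independent, which the labels do not state, so a difference shared by a group's libraries for another reason would give the same outcome. At 6 h against untreated roots the real count was 2412 and the highest of the others 902. The real and highest other counts were 2944 and 881 for 30 h against 6 h, 582 and 411 for 54 h against 30 h, and 3156 and 721 for 54 h against 6 h. Against untreated roots they were 4729 and 1917 at 30 h, and 6077 and 1621 at 54 h. These splits do not separate a change in the roots from a difference in how many genes a library lists.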

How the results depend on the processing

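The counts of calls at 6 h against untreated roots (2412) moved by over 1.5 times to 5085 with no filter, 1358 with quantile normalization, 284 among genes above 0 in every library, 237 among those with median-ratio scaling and 906 with zeros as missing. Those of 30 h against 6 h (2944) moved to 1518 with median-ratio scaling, 4831 with array weights, 710 among genes above 0 in every library, 319 with scaling as well, 863 with zeros as missing and 131 without the libraries listing under 5000 genes. Those of 54 h against 30 h (582) moved to 230 with quantile normalization, 347 with only the 2 groups compared, 932 with array weights and 913 with zeros as missing. Those of 54 h against 6 h (3156) moved to 583 among genes above 0 in every library, 666 with scaling as well and 1611 with zeros as missing. Those of 30 h against untreated roots (4729) moved to 7565 with no filter, 255 among genes above 0 in every library, 407 with scaling as well, 687 with zeros as missing and 2149 without the libraries listing under 5000 genes. Those of 54 h against untreated roots (6077) moved to 616 among genes above 0 in every library, 842 with scaling as well and 2128 with zeros as missing. Settings on zeros and on genes above 0 in every library tested fewer genes, which does not explain the higher count with zeros as missing at 54 h against 30 h; the cause was not tested.

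Leaving out each untreated replicate gave 1568 to 1879 calls at 6 h, 2405 to 3334 at 30 h and 3863 to 4724 at 54 h, lowest each time without replicate 2; at 30 h, 3147 were called without replicate 4. The difference in genes listed at 6 h, -5360, was -5748 to -4904 without 1 untreated replicate, and -3682 for genes at 1 FPKM or more.

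Replicate numbers did not pair the libraries: over 39 same-numbered pairs the correlation of deviations ran from -0.36 to 0.27, and 9 of 78 searches found the own number best. With the replicate number as a block, the calls numbered 1970, 2664, 496 and 2912 for the first 4 comparisons, and 3144 and 4643 at 30 and 54 h against untreated roots. Of these, 3144 is over 1.5 times from the 4729 without the block, and the other 5 are within it.

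Over named loci, identifiers and families, 194 of 242 alternative values kept their direction and side of the threshold, 44 kept their direction but no longer passed, 1 kept it and newly passed, and 3 changed direction. These were the family totals of MIR398 and MIR408 at 30 h against 6 h, -0.77 and -0.11 without the libraries listing under 5000 genes, and that of MIR398 at 6 h against untreated roots, 0.13 with quantile normalization, none past the threshold in any setting. Without the 30 h libraries nearer another group, the 6 counts of calls stayed within 1.5 times. The tests of gene lists were not run, as no list had a member.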

Other observations

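The tests on family totals, on profiles and on each of MIR398 and MIR408 alone were chosen after seeing the data, while the tests of explanations for both families together were set down before their results were seen. Of 18 microRNA family totals, 1 rose and 1 fell from 6 to 54 h. The MIR408 total, which is that of zma-MIR408b alone, rose by 2.45 on the log2 scale (permutation test, adjusted p = 0.02), and the MIR167 total fell by 1.34 (permutation test, adjusted p = 0.023). MIR167 was at 0.351 to 8.84 FPKM at 6 h and at 0 to 3.31 FPKM at 54 h, where 3 libraries listed it at 0. Whether libraries with few listed genes gave this fall was not tested. MIR408 passed under all 4 other settings run, and MIR167 under 3, but not with quantile normalization (-0.49, permutation test, adjusted p = 0.11), which called 9 families higher and 0 lower. Quantile totals held only the loci tested by limma, for MIR167 zma-MIR167b and zma-MIR167g, where the main total drew on 9 loci above 0. The lost call and the counts of families with this setting can therefore also come from the change of loci. The totals of MIR398 and MIR408 kept their loci. The MIR398 total was at 28.9 ± 28.2 FPKM at 54 h against 3.65 ± 4.66 at 6 h (SD, n = 10 in each), a log2 difference of 2.1 that did not pass (permutation test, adjusted p = 0.078) and passed only with quantile normalization (adjusted p = 0.0045, 0.077 to 0.16 in the other 3). In the main setting no family passed in the other 3 comparisons, where 3, 4 and 3 families had an unadjusted permutation p under 0.05. At 6 h against untreated roots these 3 were lower. Quantile normalization called 8 families higher and 0 lower there, and it moved the median of all genes tested from -0.28 to 0.12. MIR408, 1 of these 3, stayed lower with it, at -0.64. At 54 h against 30 h it called 1 family higher.

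The MIR398 and MIR408 totals were higher at 54 h than at 6 h, but past the test in the main setting for MIR408 alone. After median-ratio scaling the differences were 1.03 and 1.00 times the unscaled ones. Scale factors ran from 1 to 1.39 at 6 h with the fungus and from 0.85 to 1.33 at 54 h. Factors this alike could hardly have lowered the differences much, so library scaling is argued against only as far as these factors measure it. After quantile normalization the differences were 1.35 and 1.22 times the unscaled ones. That setting called 9 families higher and 0 lower here, so these ratios are no evidence on these 2 families. Libraries with few listed genes are argued against as the whole source for MIR408 and stay open for MIR398. The 3 libraries of 54 h that listed 9667 to 10400 genes, within the range of 6 h, had MIR408 totals of 15.6 to 22.5 FPKM against at most 6.14 at 6 h, a log2 difference of 3.10 (exact permutation test, p = 0.007). Their MIR398 totals ran from 0.436 to 31.9 FPKM against at most 15.9 at 6 h, a log2 difference of 0.33 (exact permutation test, p = 0.71), and 3 libraries are too few to decide. Within 54 h the Spearman rho with the number of genes listed was 0.12 for MIR408 (permutation p = 0.76) and -0.50 for MIR398 (permutation p = 0.14). Pearson r was 0.38 for MIR408 (permutation p = 0.3), or 0.33 without the 2 libraries farthest from the median, and -0.48 for MIR398 (permutation p = 0.15), or -0.58 without them. The sum of both families had a Spearman rho of -0.42 with the number of genes listed (permutation p = 0.23) and a Pearson r of -0.24 (permutation p = 0.51), or -0.33 without the 2 libraries farthest from the median. Plant age or hours in the jar cannot be told apart from the fungus, as 0 untreated libraries later than 6 h were analysed here.

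The genes that rose at 6 h were followed against treated libraries of 6 h that had not been used to call them. The libraries of 30 and 54 h entered the calling fit through the shared spread only. Of 223 genes higher in treated replicates 1 to 5 than in untreated roots, 52 were lower at 30 h and 4 higher than in treated replicates 6 to 10 of 6 h, and 43 were lower and 18 higher at 54 h. Over all 14224 genes tested, 902 were lower at 30 h and 1683 at 54 h in the same fits. The median log2 difference of the 223 genes was -0.68 at 30 h and -0.16 at 54 h, against -0.62 and -0.55 for all genes. Among genes above 0 in every library, after scaling, 88 rose in replicates 1 to 5, of which 13 were lower and 11 higher at 30 h, and 13 lower and 21 higher at 54 h. Over all 1903 of these genes, 55 were lower at 30 h and 125 at 54 h.

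Over the 1903 genes above 0 in every library, each library was set against the means of the other libraries of every group. All 3 untreated, all 10 treated libraries of 6 h and all 10 of 54 h correlated best with their own group, across genes, which are not independent replicates. Of the 30 h libraries 7 of 10 did. Replicate 4 of 30 h correlated best with the 6 h treated group (r = 0.5, against -0.27 with its own group), replicate 7 with the 54 h group (r = 0.55 against 0.39) and replicate 5 with untreated roots (r = 0.17 against 0.07). Single genes went both ways on a plain exchange of labels. Replicate 7 was at 435 FPKM for Zm00001d036542, within the 170 to 691 of 54 h, where the other 9 libraries of 30 h were at 0. Replicate 4 was at 34.6 FPKM for Zm00001d033855 and 66 for Zm00001d015905. Treated libraries of 6 h ran from 31 to 88.8 and from 30.9 to 134 for them. Other genes went against an exchange. Zm00001d031157 was at 11.5 FPKM in replicate 4 and at 20.4 in replicate 5, where treated libraries of 6 h reached 4.25 and untreated ones 0.578. Zm00001d053881 was at 39.5 FPKM in replicate 4 and at 0 in all treated libraries of 6 h. Zm00001d042114 was listed at 0 in replicate 7, where libraries of 54 h were at 174 to 692 FPKM. Neither wrong labels nor a difference in how far contact had gone was tested. Leaving these 3 out gave 4176 calls for 30 h against 6 h in place of 2944, a choice made by the profiles themselves, which favours more calls.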
